A study of Mus musculus with 6 samples.

How the data were processed

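Polyadenylated transcripts were profiled by RNA sequencing in 6 samples of EO771 cells, a mouse mammary tumour line. Per the labels, 3 libraries came from untreated cells and 3 from cells given recombinant lipocalin-2 (LCN2) protein. The labels give a replicate number from 1 to 3 in each group and name no dose, exposure time, batch or day. Per the labels' protocols, RNA was purified with an RNeasy kit and libraries were built with a SMARTer mRNA kit. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

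The authors deposited 1 table with a value for each of 19832 genes in each library. Its name describes raw counts, but 0% of the values above 0 were whole numbers within a tolerance of 1e-9, and the values were treated here as FPKM, fragments scaled to transcript length and library size. This unit was inferred from the deposited values and is stated by neither a header nor a label. Each column summed to between 391569 and 410808, and the values multiplied by annotated transcript length in kilobases summed to between 1032628 and 1095179. Per the submitters' processing notes the genome build was GRCm38. The aligner, the quantifier and their versions are not given in the sources used here, nor is the treatment of strand. Gene IDs were matched to the GENCODE M21 annotation of GRCm38, where 19798 were found and 34 were not. Of those found, 19768 were protein coding, so RNAs of other classes were largely not analysed here.

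The number of reads per library is unknown. Whole reads were looked for among genes of low value with a single annotated transcript, where the ratio of values between libraries would repeat if whole reads had been counted. The commonest ratio held between 4 and 7 of 481 to 508 genes at a tolerance of 0.002 on the log2 scale, so relative depth was not recovered. Intervals and detection floors that need read counts are therefore not given. In 5744 genes the value was listed at 0 in every library, which in such a table can also be a failed estimate.

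The design written before the data were examined assumed counts and fixed a quasi-likelihood count test with TMM scaling (trimmed mean of M-values). Because the table does not hold counts, that test was not used, and limma 3.58.1 in R 4.3.3 was used in its place. The values were first fitted as deposited, with no scaling between libraries. That fit called 693 genes higher and 1680 lower. TMM scaling, which the design had fixed, was made the reported setting only after that split was seen, and both splits are given with the results. The TMM factors were computed without the weights that need counts, trimming a share of 0.3 of the ratios and 0.05 of the mean levels at each end, and lay between 0.970 and 1.06. Reported tests used log2(FPKM + 1) after this scaling, genes with a mean of at least 1 FPKM over the 6 libraries (10309 genes), a variance trend and no replicate term. The pseudocount, the filter and the unweighted form of TMM were chosen after the table was seen, the first 2 of them before any fit. Calls are at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A log2 fold change is LCN2 minus control on the log2(FPKM + 1) scale, which understates the change of genes of low value. Group means ± SD are of FPKM as deposited (n = 3 in each group), and every adjusted p of a gene is from limma.

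Lists of genes, 55 in number, were written before the data were examined. In all, 78 of their entries had no match in the table and are not analysed here, the LCN2 receptor gene Slc22a17 and both mitochondrial rRNAs among them. The 47 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Where only the threshold is named below, a list's adjusted p is from camera with the preset correlation.

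Genes were named by a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes with at least 5 units in the higher group (CPM in the rule, applied here to FPKM) and no overlap between the groups after scaling, leaving out predicted gene models by their symbols. It also takes Lcn2 and its receptors, and in each list up to 4 called members with the smallest adjusted p, or up to 2 members given as values where none was called. Any other gene named was chosen after its values were seen, and the text says so. Some genes that the rule takes are not reported here. For genes that the rule takes, overlap of exons with those of another annotated gene is pointed out once in the results, since the table cannot separate such reads. Other genes were not checked for it. The pattern fixed for the symbols of predicted gene models takes 412 tested genes, but 95 of them are taken only because they end in ps and digits, Rps, Mrps and Vps genes among them, and these are not predicted models. Called genes among these 95 changed by at most 0.39 on the log2 scale, too little for the largest rises and falls.

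The procedure was tested on simulated data, in 5 runs with 200 of the 10309 genes changed. It recovered 89.2% of genes changed by 0.5 on the log2 scale and 99.6% of those changed by 1, with 5.11% of the calls false and 0 calls of the wrong sign. Of 250 random lists, 8 had a camera p under 0.05. The simulated noise was drawn independently for each gene and library. In the data the estimated correlation was 0.79 for the immediate early genes and 0.73 for the integrated stress response list. How the calls and list tests behave with correlated genes, or with libraries of differing spread, was therefore not tested. Changes smaller than 0.5 and a larger number of changed genes were not simulated either. The data gave 2216 calls with a median size of 0.31, so recovery and the false share were not tested for most of them.

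Alternatives fixed beforehand and run were median-ratio scaling, values as deposited in place of library totals, no filter on low values, predicted gene models left out, a replicate block, each library left out in turn, stricter thresholds, the other list tests and adjustment over a list alone. Further alternatives were chosen after seeing the data: a pseudocount of 0.1, filters at a mean of 0.1 and 5 FPKM, scaling to column sums, quantile normalization, no variance trend, array weights, a GC and length correction, and predicted gene models left out by a narrower pattern that keeps the 95 genes. Gene lists by theme written after the values were seen appear only in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.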

Results

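LCN2 is a secreted protein that binds iron-carrying siderophores and is released by several kinds of immune cell. The series concerns LCN2-positive mast cells in lymph nodes, stemness of cancer cells and a peptide of mitochondrial origin, and this comparison asks how the transcriptome of EO771 mammary tumour cells differs when recombinant LCN2 is added. There were 3 control and 3 LCN2 libraries. Between 13299 and 13461 genes had a value above 0 in each library, and between 10251 and 10340 reached 1 FPKM. Mitochondrial mRNAs made up between 8.82% and 9.03% of each library's summed FPKM.

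The transcripts of LCN2 itself and of the receptors Lrp2 and Mc4r were at or near 0 in these cells. Lcn2 (chromosome 2, 32384633 to 32388252, GRCm38) had 0.0891 ± 0.0328 FPKM (SD, n = 3) in control cells and 0.276 ± 0.0347 FPKM (n = 3) in LCN2-treated cells, below the level required for testing. All 3 treated libraries lay above all 3 controls, which gave p = 0.1 in a two-sided exact permutation test, the smallest value that 3 against 3 allows. In limma without the filter on low values Lcn2 passed (adjusted p = 0.022, and adjusted p = 0.023 with a pseudocount of 0.1 in addition). The receptor gene Lrp2 was at 0.0153 ± 0.00233 FPKM in control and 0.00643 ± 0.00657 FPKM in treated cells, and Mc4r was listed at 0 in every library. Slc22a17 was not analysed here.

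Among 10309 genes tested, 2216 changed with LCN2, of which 1213 were higher and 1003 lower. Most changes were small. The median size among changed genes was 0.31 on the log2 scale, and 40 genes changed by 1 or more, 36 of them upwards and 4 downwards. Without scaling between libraries, 693 genes were higher and 1680 lower, so that 70.8% of the calls were falls in place of 45.3%, while the median log2 fold change of all genes moved from 0.0008 to -0.056. Scaled to column sums 950 were higher and 1308 lower, and after quantile normalization 1109 higher and 1164 lower. Falls thus outnumbered rises in 3 of the 5 scalings, all but TMM and median-ratio scaling (1188 higher, 1045 lower). The split between rises and falls therefore depended on the scaling. The groups did not overlap in 44.6% of genes, where chance gives 10% for 3 against 3. The number of calls also depended on the libraries used. It was 653 without control replicate 1, 456 without control replicate 3, 268 without LCN2 replicate 1 and 488 without LCN2 replicate 3, and 3160 without LCN2 replicate 2. Of the 162 named genes that were called, 49 were called in all 6 fits that left out 1 library. The call was lost by 71 named genes without control replicate 1, 11 without control replicate 2, 83 without control replicate 3, 113 without LCN2 replicate 1, 2 without LCN2 replicate 2 and 87 without LCN2 replicate 3.

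**Figure D1:**
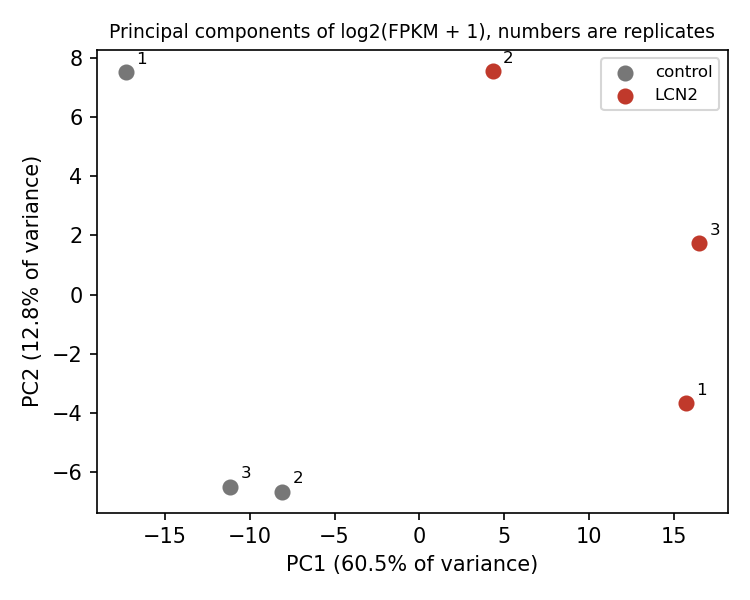
Principal components of log2(FPKM + 1) over the 10309 tested genes, with 1 point per library, grey for control and red for LCN2, and the replicate number beside it. The first component (60.5% of the variance) separates the groups, with LCN2 replicate 2 at 4.34, between the controls (-17.3 to -8.09) and the other LCN2 libraries (15.7 and 16.5).

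LCN2 replicate 2 lay between the groups on the first principal component, at 4.34, where the other LCN2 libraries were at 15.7 and 16.5 and the controls between -17.3 and -8.09. Its correlation with the other LCN2 libraries across genes was 0.992 and 0.993, and with the controls it was between 0.988 and 0.992. Genes are not independent replicates, so these correlations describe the libraries only.

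On the log2(FPKM + 1) scale, the largest rise among genes named by the rule was in Nupr1, a stress-induced nuclear protein (chromosome 7, 126623249 to 126630861), from 12.3 ± 4.88 to 68.0 ± 21.5 FPKM (log2 fold change 2.46, SE 0.31, adjusted p = 0.0058). Soat2, an enzyme that esterifies cholesterol, rose from 1.01 ± 0.524 to 7.31 ± 2.32 FPKM, by 2.09 on the log2 scale. The growth factor gene Csf2 rose from 15.9 ± 6.84 to 51.8 ± 14.4 FPKM and the YAP-responsive gene Ankrd1 from 97.2 ± 23.1 to 297 ± 61.9 FPKM. Complement component C3 (chromosome 17, 57203970 to 57228136) had the smallest adjusted p of these genes, at 0.00021, and rose from 6.43 ± 0.404 to 21.2 ± 1.51 FPKM. The other large rises were in Trib3 (1.56), Gdf15 (1.51), Txnip (1.51), Slc6a9 (1.46), Adamts1 (1.40), Chchd10 (1.38) and Mmp13 (1.31), given as log2 fold changes. Exons of Csf2, Txnip, Slc6a9 and Chchd10 overlap those of other annotated genes. Nupr1, Soat2, Ankrd1, C3, Adamts1 and Mmp13 were called whichever library was left out. Trib3 was no longer called without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, with an adjusted p of up to 0.075. Gdf15 and Txnip were no longer called without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.080 and 0.088). Csf2, Slc6a9 and Chchd10 were no longer called without LCN2 replicate 1 (adjusted p = 0.055, 0.055 and 0.061).

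Falls among the named genes were mostly smaller. Ankrd37, a gene induced in hypoxia, fell from 5.82 ± 3.11 to 1.17 ± 0.781 FPKM (log2 fold change -1.54, SE 0.41, adjusted p = 0.038), but control replicate 2 (2.24 FPKM) was close to LCN2 replicate 2 (2.07 FPKM) and the call was lost in 4 of the 6 fits that left out 1 library, with an adjusted p of up to 0.13. Apela, which encodes a ligand of the apelin receptor, fell from 33.2 ± 2.13 to 12.4 ± 1.41 FPKM (log2 fold change -1.29, adjusted p = 0.0015). Albumin mRNA (Alb, chromosome 5, 90460897 to 90476602) was abundant in these tumour cells and fell from 335 ± 20.2 to 185 ± 7.58 FPKM (log2 fold change -0.78, SE 0.04, adjusted p = 0.00039). The chaperone gene Hspa8 fell from 840 ± 77.5 to 433 ± 148 FPKM. The remaining large falls were in Ly6f (-0.91), Mxd3 (-0.89), Wdr6 (-0.88), Rnase4 (-0.81), Hexim1 (-0.80), Acnat2 (-0.80), Acat2 (-0.80) and Scd2 (-0.78). Hspa8 was not called without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.082), Acnat2 without LCN2 replicate 1 or LCN2 replicate 3 (up to 0.058), Acat2 without control replicate 3 or LCN2 replicate 1 (up to 0.059), and Wdr6 and Scd2 without LCN2 replicate 1 (0.055 and 0.052). Exons of Ankrd37, Apela, Hspa8, Mxd3, Wdr6, Rnase4, Acnat2 and Scd2 overlap those of other annotated genes, and Rnase4 shares exons with Ang.

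**Figure D2:**
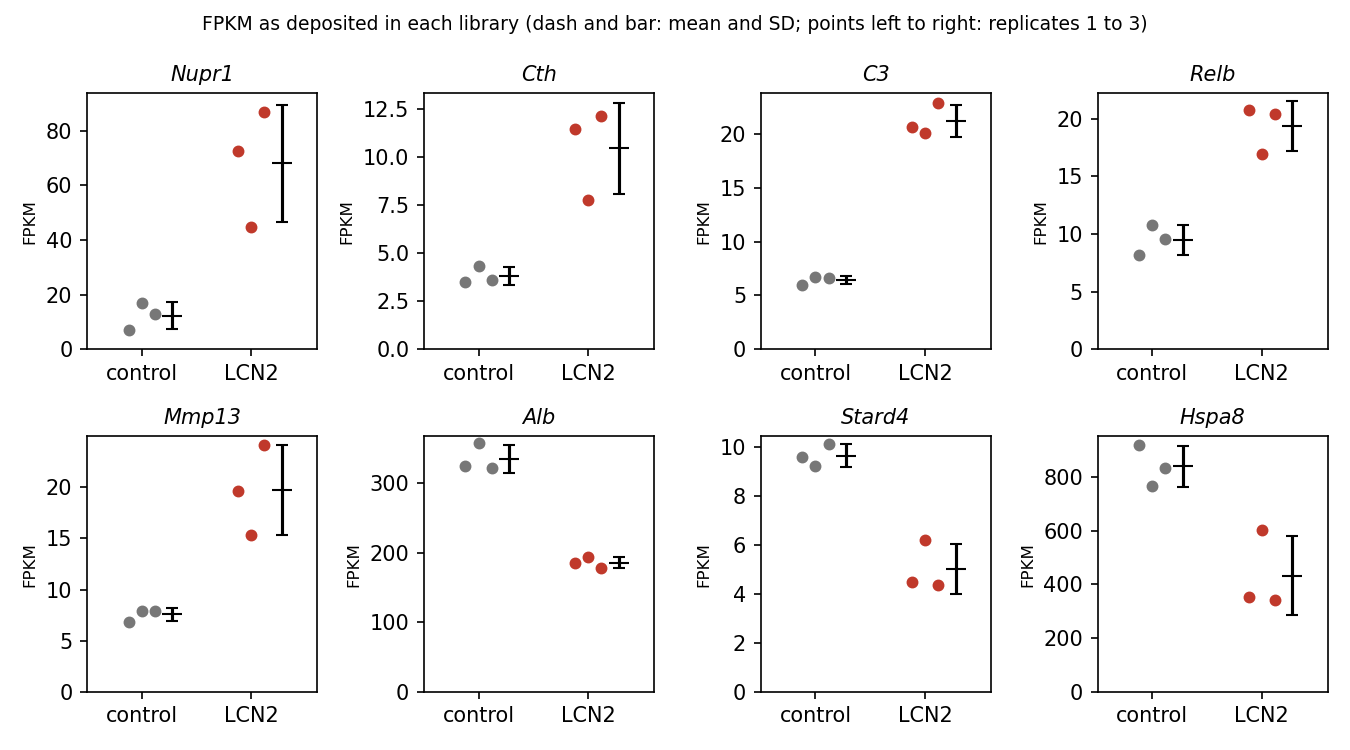
FPKM as deposited (linear axes from 0) of 8 genes in the 3 control (grey) and 3 LCN2 (red) libraries, with 1 point per library and the mean ± SD beside each group. Nupr1, Cth, C3, Relb and Mmp13 were higher and Alb, Stard4 and Hspa8 lower in LCN2 libraries, and for Hspa8 LCN2 replicate 2 (603 FPKM) lay nearest to the controls.

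The integrated stress response, through which the transcription factor ATF4 induces amino acid synthesis and transport genes, had the highest median change of the lists tested. Of its 28 tested members 22 rose and 0 fell, with a median log2 fold change of 0.74, and 26 rose when adjusted over the list alone. Besides Nupr1, the cysteine-forming enzyme Cth rose from 3.81 ± 0.471 to 10.5 ± 2.37 FPKM (1.29 on the log2 scale, adjusted p = 0.0055). The mitochondrial folate enzyme Aldh1l2 rose from 0.943 ± 0.128 to 2.88 ± 0.549 FPKM and the tryptophanyl-tRNA synthetase Wars from 124 ± 7.71 to 153 ± 11.3 FPKM. Atf4 itself rose by 0.54 (adjusted p = 0.021), while Chac1 (1.67, adjusted p = 0.063), Atf3 (1.25, adjusted p = 0.051) and Ddit3 (0.90, adjusted p = 0.051) did not pass. These last 4 genes were chosen after their values were seen. The list passed camera (adjusted p = 4.8e-11), and adjusted p = 0.50 with an estimated correlation. The 22 rises became 13 without control replicate 1, 5 without control replicate 3, 4 without LCN2 replicate 1 and 6 without LCN2 replicate 3, and 26 without LCN2 replicate 2. Exons of Aldh1l2 overlap those of other annotated genes.

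Among stress genes of other compartments, cytosolic heat shock genes mostly fell, and those of the endoplasmic reticulum and of mitochondria went both ways. Of 19 tested endoplasmic reticulum chaperone and folding genes, 2 rose and 2 fell, as they did when adjusted over the list alone, and without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 no member was called. Hspa5 was higher by 0.40 and Xbp1 by 0.27, while Calr fell by 0.14 and Pdia6 by 0.13, and the list did not pass (adjusted p = 0.96). Its median of 0.0009 and mean of 0.05 were above 0 and its test pointed down, and the median was below 0 under the other scalings. Cytosolic heat shock genes fell in 7 of 10 members and rose in 0, and in 8 when adjusted over the list alone. Hspa8 (-0.94), Dnaja1 (-0.61), Hsph1 (-0.55) and Dnajb1 (-0.55) were the called members with the smallest adjusted p (list adjusted p = 0.00077, adjusted p = 0.50 with an estimated correlation and adjusted p = 0.062 with fry for direction). None of the heat shock genes was called without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3. Of 11 genes of the mitochondrial unfolded protein response, Lonp1 (0.54) and Hspa9 (0.41) rose and Hspd1 fell by 0.15, the same counts as when adjusted over the list alone (list adjusted p = 0.52). The median of that list was 0.02 and turned to -0.04 with values as deposited. The call of Pdia6 was lost without control replicate 1, control replicate 2, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.12). The calls of Hspa5, Xbp1, Calr, Hspa8, Dnaja1, Hsph1, Dnajb1 and Hspd1 were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.15). The call of Hspa9 was lost without LCN2 replicate 1 (adjusted p = 0.055). Exons of Pdia6, Dnaja1 and Hspd1 overlap those of other annotated genes.

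Targets of NF-kB and acute inflammation rose in 17 of 24 tested members, with 0 falls and a median log2 fold change of 0.49. When adjusted over the list alone, 18 rose and 1 fell. Relb, an NF-kB subunit, rose from 9.50 ± 1.29 to 19.4 ± 2.15 FPKM (1.02 on the log2 scale, adjusted p = 0.0040). The precursor gene Nfkb2 rose by 0.51 and the inhibitor gene Nfkbie by 0.79, and C3 belongs to this list too. The list passed camera (adjusted p = 6.8e-09), and adjusted p = 0.50 with an estimated correlation. The count was 9 without LCN2 replicate 1 and otherwise between 12 and 18. Genes of the IL6/STAT3 pathway rose in 7 of 12 members and fell in 0, among them Lif (0.86), Junb (0.85), Bcl3 (0.66) and Il6st (0.36), with a list adjusted p of 0.010 and adjusted p = 0.50 with an estimated correlation. With p adjusted over the list alone, 7 rose and 1 fell. Without LCN2 replicate 1, 0 of the IL6/STAT3 genes were called, 1 without LCN2 replicate 3, 2 without control replicate 3 and 3 without control replicate 1. The call of Il6st was lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.085). The call of Bcl3 was lost without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.064). The call of Junb was lost without LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.059). The call of Lif was lost without LCN2 replicate 1 (adjusted p = 0.052). Exons of Nfkb2, Junb and Bcl3 overlap those of other annotated genes.

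No interferon-response gene was called higher. Of 19 tested members 0 were higher and 1, Ifi27l2a, was lower (-0.63, adjusted p = 0.041), and the list did not pass (adjusted p = 0.96; its median of -0.05 and its test differ in sign). In tests adjusted over the list alone, 0 changed. Among 10 tested genes of MHC class I presentation, B2m rose by 0.27 and H2-T22 fell by 0.31 (list adjusted p = 0.23), and 4 rose and 1 fell when adjusted over the list alone. The call of Ifi27l2a was lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.13). The call of H2-T22 was lost without LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.062). Exons of H2-T22 overlap those of other annotated genes.

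Immediate early genes, which respond within minutes to growth factor or stress signals, rose in 11 of 21 members and fell in 0 (median 0.60, list adjusted p = 3.6e-07, adjusted p = 0.50 with an estimated correlation and adjusted p = 0.076 with fry for direction). For p-values adjusted over the list alone, 19 rose. Fosl1 rose by 1.16, Junb by 0.85, Ier3 by 0.68 and Myc by 0.66. The count was 3 without control replicate 3 and 1 without either LCN2 replicate 1 or LCN2 replicate 3. Targets of YAP/TEAD rose in 6 of 10 members, with Ankrd1 (1.67), Ccn2 (0.77), Axl (0.49) and Crim1 (0.40) (list adjusted p = 0.00016, and adjusted p = 0.50 with an estimated correlation). TGF-beta targets rose in 4 of 10, among them Ccn2, Tgif1 (0.53) and Tgfb1 (0.44) (list adjusted p = 0.0043, and adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone, 7 YAP/TEAD and 4 TGF-beta targets rose. The YAP/TEAD count was 3 without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, and the TGF-beta count 2 without LCN2 replicate 1. Of 3 tested Notch targets 1 rose, Jag1 (0.64), and the list did not pass (adjusted p = 0.063), with 2 rises when adjusted over the list alone. It passed with values as deposited (adjusted p = 0.027), scaled to column sums (adjusted p = 0.046), after quantile normalization (adjusted p = 0.049), with a filter at a mean of 0.1 FPKM (adjusted p = 0.047) and without control replicate 2 (adjusted p = 0.033), and with an estimated correlation its adjusted p in these 5 fits was between 0.42 and 0.61. The call of Tgif1 was lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.086). The calls of Myc and Crim1 were lost without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.065). The calls of Fosl1 and Junb were lost without LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.059). The calls of Tgfb1 and Jag1 were lost without LCN2 replicate 1 (adjusted p of up to 0.055). Exons of Fosl1, Ccn2 and Crim1 overlap those of other annotated genes.

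Genes for matrix proteases and their inhibitors rose in 10 of 15 members and fell in 1 (median 0.44, list adjusted p = 2.2e-05, and adjusted p = 0.50 with an estimated correlation). With p adjusted over the list alone, 12 rose and 1 fell. The metalloproteases Adamts1 and Mmp13 rose from 8.41 ± 1.75 to 22.8 ± 4.07 FPKM and from 7.57 ± 0.613 to 19.7 ± 4.38 FPKM. The plasminogen activator gene Plat rose by 0.57 on the log2 scale. The count was 6 without control replicate 3 and 5 without LCN2 replicate 1. Matrix and collagen genes gave 2 rises and 1 fall among 11, with Dcn (0.30) and Fn1 (0.27) higher and Thbs1 (-0.30) lower (list adjusted p = 0.96), as when adjusted over the list alone. Its median of 0.0024 was above 0 while its test pointed down, and the median was below 0 under the other scalings. Mesenchymal genes gave 3 rises and 1 fall among 11, with Itga5 (0.24), Fn1 and Zeb2 (0.44) higher and the intermediate filament gene Vim lower, from 309 ± 3.81 to 235 ± 9.14 FPKM (list adjusted p = 0.50). In tests adjusted over the list alone, 3 mesenchymal genes rose and 2 fell, and 0 rises were called without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3. Epithelial genes gave 5 rises and 3 falls among 14. The tight junction genes Cldn4 (1.23) and Cldn3 (0.47) rose, and the keratin genes Krt8 (-0.27) and Krt19 (-0.22) fell (list adjusted p = 0.62). For p-values adjusted over the list alone, 6 epithelial genes rose and 4 fell, and without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 there were 2 rises and at most 1 fall. Without control replicate 2 there were 3 rises. The calls of Fn1, Itga5, Zeb2 and Krt19 were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.11). The call of Thbs1 was lost without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.081). The call of Krt8 was lost without LCN2 replicate 1 (adjusted p = 0.052). Exons of Fn1, Thbs1, Zeb2, Cldn3 and Krt8 overlap those of other annotated genes.

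Genes used as markers of cancer stem cells, the property named in the title of the series, rose in 7 of 20 tested members and fell in 2. The list's median was 0.09 and its adjusted p was 0.017, with adjusted p = 0.50 for an estimated correlation, and 7 rose and 3 fell when adjusted over the list alone. The rises included the drug efflux transporters Abcb1a (8.40 ± 0.591 to 12.4 ± 0.672 FPKM, 0.57 on the log2 scale), Abcb1b (0.47) and Abcg2 (0.60), and the surface receptor Procr (55.7 ± 2.97 to 76.6 ± 4.28 FPKM, 0.51). The members that fell were Cd24a (-0.55) and Lgr5 (-0.31), and Aldh1a1 (-0.03, adjusted p = 0.66), Cd44 (0.02, adjusted p = 0.74) and Sox9 (0.01, adjusted p = 0.88) did not pass. These 5 genes were chosen after their values were seen. Pou5f1 and Sox2, chosen in the same way, were listed at 0 in every library. The 7 rises became 4 without control replicate 3 and 3 without either LCN2 replicate 1 or LCN2 replicate 3, and 0 falls were called without control replicate 1 or any of these. Wnt/beta-catenin targets, many of which are feedback inhibitors or stem cell markers, fell in 7 of 10 members and rose in 1, also when adjusted over the list alone. Nkd1 fell from 77.2 ± 5.68 to 47.9 ± 0.703 FPKM (-0.61, adjusted p = 0.0032), and Notum (-0.71), Rnf43 (-0.67) and Tnfrsf19 (-0.46) fell with it. The Wnt list passed camera (adjusted p = 0.00061), and adjusted p = 0.50 with an estimated correlation. The Wnt falls numbered 4 without control replicate 3, 2 without LCN2 replicate 1 and 3 without LCN2 replicate 3. Drug efflux and detoxification genes gave 4 rises and 1 fall among 14 (list adjusted p = 0.14), the rises being Abcb1a, Abcb1b, Abcg2 and Tiparp (0.24). That list passed fry for direction (adjusted p = 0.023). Adjusted over the list alone, 6 rose and 1 fell, and 2 rises were called without LCN2 replicate 1 or LCN2 replicate 3. The median of the efflux list was 0.03 and turned to -0.02 with values as deposited. The call of Tiparp was lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.085). The calls of Abcg2 and Rnf43 were lost without LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.068). The call of Tnfrsf19 was lost without LCN2 replicate 1 (adjusted p = 0.052). Exons of Abcb1a, Abcb1b, Notum and Tiparp overlap those of other annotated genes.

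**Figure D3:**
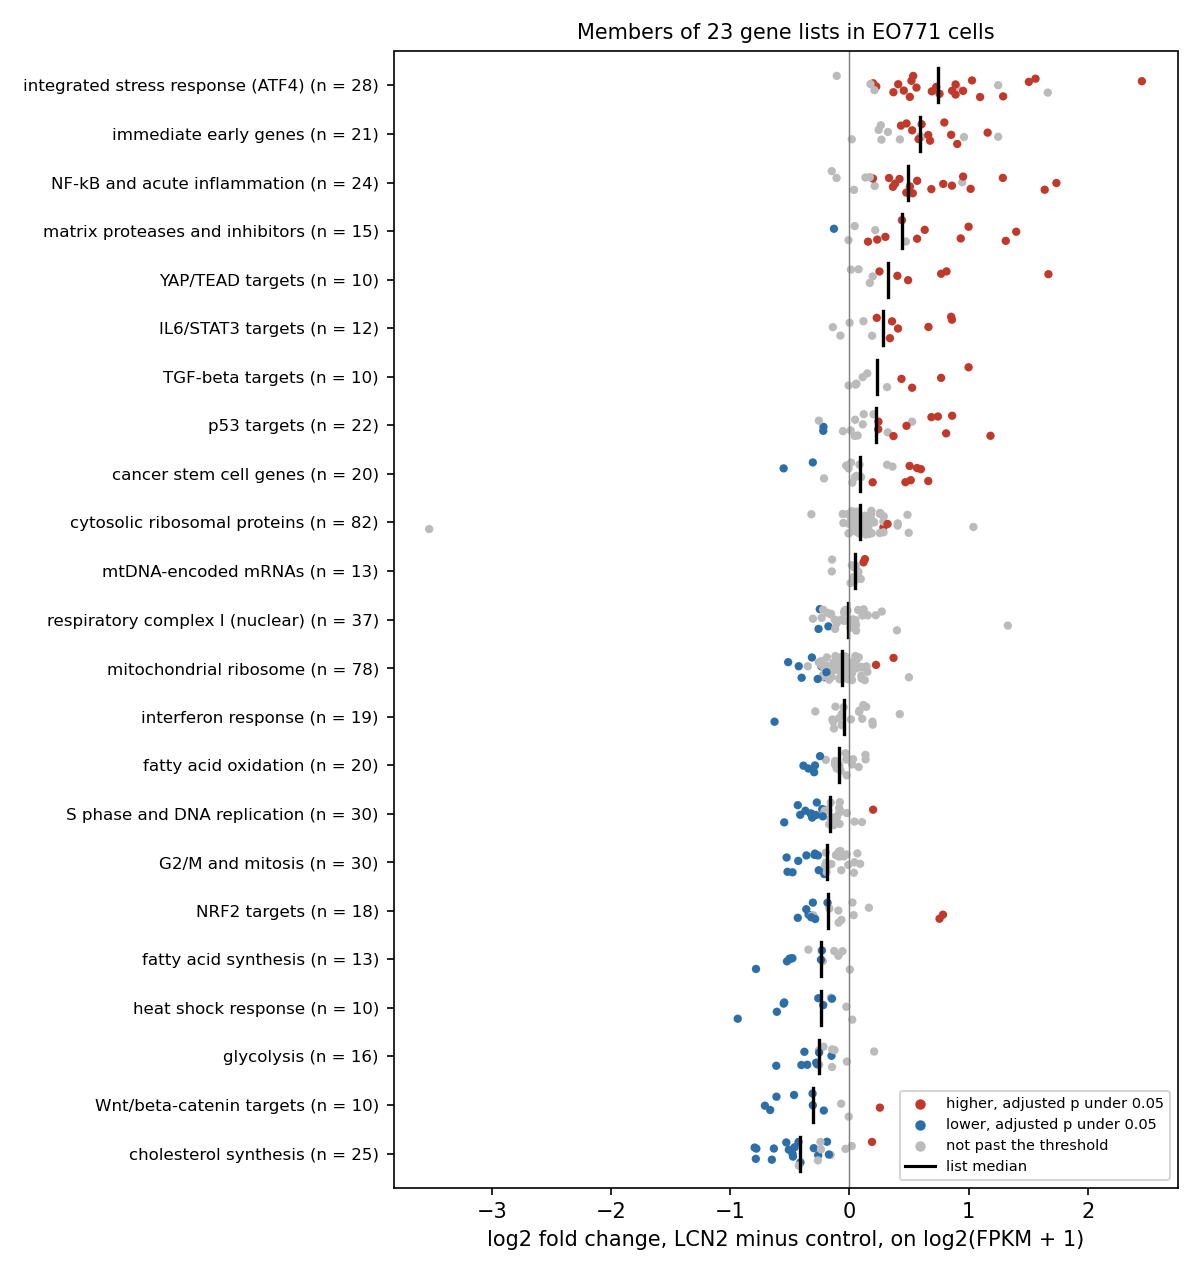
Log2 fold change (LCN2 minus control, on log2(FPKM + 1)) of each tested member of 23 gene lists, with the number of members after each name, red for higher and blue for lower at an adjusted p under 0.05, grey otherwise, and a black line at the median. The medians run from 0.74 for the integrated stress response to -0.41 for cholesterol synthesis. The single point far to the left is Rps28 (-3.53, adjusted p = 0.079), which is named here after its values were seen.

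Transcripts of the mitochondrial genome hardly differed. Of 13 mtDNA-encoded mRNAs, mt-Cytb (2430 ± 90.6 to 2544 ± 51.0 FPKM, 0.13 on the log2 scale) and mt-Nd5 (0.12) were higher and 0 were lower, also when adjusted over the list alone (list adjusted p = 0.22). With values as deposited 0 were higher and 2 lower, and the list's median moved from 0.04 to -0.02, so no direction is given for this group. Nuclear genes of complex I gave 0 rises and 3 falls among 37, Ndufa9 (-0.18), Ndufa8 (-0.25) and Ndufa5 (-0.26), and 0 of either when adjusted over the list alone (list adjusted p = 0.68; its mean of 0.02 and its median of -0.02 differ in sign). Complexes II and III gave 2 rises, Uqcrq (0.42) and Sdhb (0.20), and 1 fall, Sdha (-0.14), among 14 (list adjusted p = 0.51). In complex IV Cox7a2l rose by 0.17 and Cox7a2 fell by 0.28 among 11 (list adjusted p = 0.96, with a median of 0.01 and a mean of -0.01). ATP synthase genes gave 0 rises and 2 falls among 16, Atp5g1 (-0.24) and Atp5c1 (-0.12) (list adjusted p = 0.32). With p adjusted over the list alone, complexes II and III gave 2 rises and 4 falls, complex IV 1 of each and ATP synthase 0 of either. The median of complex IV turned to -0.05 with values as deposited. Complex I and ATP synthase each passed the list threshold without control replicate 2 (adjusted p = 0.047 and adjusted p = 0.018, and adjusted p = 0.42 for both with an estimated correlation), towards lower values. Mitochondrial ribosome genes fell in 8 of 78 members and rose in 2, with Mrpl3 (-0.40), Mrpl40 (-0.51) and Mrpl18 (-0.43) lower and Mrps31 (0.37) higher. The share that fell was near that over all tested genes, of which 1003 of 10309 were lower. In tests adjusted over the list alone, 2 rose and 6 fell. The falls numbered 2 without control replicate 1 or control replicate 3, 1 without LCN2 replicate 1, 3 without LCN2 replicate 3 and 14 without LCN2 replicate 2. That list passed camera (adjusted p = 0.017), with adjusted p = 0.67 for an estimated correlation and adjusted p = 0.15 with fry for direction, and did not pass without control replicate 1 (adjusted p = 0.20). Among 17 genes of mtDNA upkeep, Twnk, the mtDNA helicase, fell by 0.32, Ssbp1 fell by 0.29 and Mterf3 rose by 0.28, the same counts as when adjusted over the list alone (list adjusted p = 0.68). Among 12 genes of mitophagy and mitochondrial dynamics, the autophagy receptor Sqstm1 rose from 162 ± 17.6 to 290 ± 47.4 FPKM and Bnip3 fell from 18.7 ± 9.56 to 4.56 ± 3.35 FPKM (list adjusted p = 0.74), with 1 rise and 2 falls when adjusted over the list alone. In control replicate 2 Bnip3 was at 8.07 FPKM, below the 8.43 FPKM of LCN2 replicate 2, and its call was lost in 4 of the 6 fits that left out 1 library. The citrate cycle list gave 2 rises among 18, Pdhb (0.16) and Dld (0.22), and 0 falls, and 0 of either when adjusted over the list alone (list adjusted p = 0.91). Pdhb encodes a subunit of pyruvate dehydrogenase, which feeds the cycle, and Dld a subunit that this enzyme shares with other complexes. The median of the citrate cycle list was 0.0042 and its mean -0.0013, and its test pointed down. Without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, no mtDNA mRNA and no gene of complex I, ATP synthase or the citrate cycle was called, and at most 1 in each of the other respiratory complex lists. Without control replicate 2 complex I gave 7 falls, and without LCN2 replicate 2 it gave 5. With values as deposited 0 citrate cycle genes rose and 2 fell, and the median was -0.06. The call of Atp5c1 was lost without any 1 of the 6 libraries (adjusted p of up to 0.14). The calls of Sdhb, Sdha, Cox7a2l, Pdhb and Dld were lost without control replicate 1, control replicate 2, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.15). The call of Ndufa5 was lost without control replicate 1, control replicate 3, LCN2 replicate 1, LCN2 replicate 2 or LCN2 replicate 3 (adjusted p of up to 0.13). The calls of mt-Cytb, mt-Nd5, Ndufa9, Ndufa8, Atp5g1, Mrpl18, Ssbp1, Mterf3 and Bnip3 were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.15). The call of Mrpl40 was lost without control replicate 1, control replicate 3 or LCN2 replicate 1 (adjusted p of up to 0.076). The call of Uqcrq was lost without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.081). The call of Mrps31 was lost without control replicate 3 or LCN2 replicate 1 (adjusted p of up to 0.056). Exons of mt-Nd5, Ndufa9, Mrpl3, Mrpl18, Twnk, Mterf3, Sqstm1 and Bnip3 overlap those of other annotated genes.

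Falls outnumbered rises among called sterol and fatty acid synthesis genes. Of 25 cholesterol synthesis genes 16 fell and 1 rose, with a median log2 fold change of -0.41, and 21 fell and 1 rose when adjusted over the list alone. The sterol carrier gene Stard4 fell from 9.66 ± 0.463 to 5.02 ± 1.04 FPKM (-0.78, adjusted p = 0.0089). Acat2, which makes acetoacetyl-CoA, fell from 6.37 ± 0.461 to 3.15 ± 0.839 FPKM, and Pmvk (-0.65) and Fdps (-0.63) of the mevalonate pathway fell too. The list passed camera (adjusted p = 1.1e-07), and adjusted p = 0.50 with an estimated correlation. Of 13 fatty acid synthesis genes 7 fell and 0 rose (list adjusted p = 2.5e-05, and adjusted p = 0.50 with an estimated correlation). For p-values adjusted over the list alone, 11 fell. The desaturase gene Scd2 fell from 252 ± 6.11 to 142 ± 29.7 FPKM, and Fads2 (-0.50), Elovl6 (-0.52) and Fads1 (-0.23) fell with it. The cholesterol falls numbered 6 without control replicate 1, 4 without control replicate 3, 2 without LCN2 replicate 1 and 7 without LCN2 replicate 3, and 20 without LCN2 replicate 2. The fatty acid falls numbered 3 without control replicate 1, control replicate 3 or LCN2 replicate 3, and 0 without LCN2 replicate 1. Fatty acid oxidation genes fell in 5 of 20 members, among them Acads (-0.29), Acaa2 (-0.39), Hadh (-0.34) and Etfdh (-0.25) (list adjusted p = 0.029, adjusted p = 0.50 with an estimated correlation and adjusted p = 0.051 with fry for direction). Adjusted over the list alone, 5 fell. The falls numbered 3 without control replicate 2, 1 without control replicate 1 or control replicate 3 and 0 without LCN2 replicate 1 or LCN2 replicate 3. The oxidation list did not pass without control replicate 2 (adjusted p = 0.091). The call of Etfdh was lost without control replicate 1, control replicate 2, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.11). The calls of Fads1 and Hadh were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.084). The call of Acads was lost without control replicate 1, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.066). The call of Acaa2 was lost without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.063). The call of Acat2 was lost without control replicate 3 or LCN2 replicate 1 (adjusted p of up to 0.059). The calls of Fdps, Scd2, Fads2 and Elovl6 were lost without LCN2 replicate 1 (adjusted p of up to 0.058). Exons of Fdps, Elovl6 and Etfdh overlap those of other annotated genes.

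Glycolysis genes fell in 8 of 16 members and rose in 0 (median -0.25, list adjusted p = 4.5e-05, adjusted p = 0.52 with an estimated correlation and adjusted p = 0.082 with fry for direction). With p adjusted over the list alone, 11 fell. Tpi1 fell from 560 ± 42.4 to 405 ± 34.1 FPKM, and Pfkl (-0.61), Hk1 (-0.28) and Pgam1 (-0.38) were lower. None of them was called without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, and 12 were called without control replicate 2. Hypoxia-response genes went both ways, with 3 rises and 7 falls among 21 and a list adjusted p of 0.31, or 6 rises and 8 falls when adjusted over the list alone. Ndrg1 (0.84) and Ddit4 (0.49) rose and Kdm3a (-0.55) and Ldha (-0.35) fell. Without control replicate 2, where Ankrd37 and Bnip3 were the lowest of the controls, the hypoxia list passed towards lower values (adjusted p = 0.018, and adjusted p = 0.42 with an estimated correlation). No hypoxia gene was called as a fall without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3. The calls of Tpi1, Pfkl, Hk1, Pgam1, Kdm3a, Ldha and Bnip3 were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.14). The call of Ddit4 was lost without control replicate 1, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.075). The call of Ndrg1 was lost without LCN2 replicate 1 (adjusted p = 0.052). Exons of Tpi1, Hk1 and Ndrg1 overlap those of other annotated genes.

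Falls outnumbered rises among called cell cycle genes, and they were small. S phase genes fell in 11 of 30 members and rose in 1, with Prim1 (48.5 ± 1.23 to 34.1 ± 2.33 FPKM, -0.43), Uhrf1 (-0.37) and Tk1 (-0.22) lower and Gins1 (0.20) higher (list adjusted p = 4.1e-05, adjusted p = 0.50 with an estimated correlation and adjusted p = 0.060 with fry for direction). G2/M genes fell in 11 of 30 and rose in 0, with Bub1b (-0.43), Mki67 (-0.36), Kif20a (-0.52) and Aurkb (-0.53) (list adjusted p = 5.5e-05, adjusted p = 0.67 with an estimated correlation and adjusted p = 0.10 with fry for direction). In both lists 14 fell when adjusted over the list alone. Without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, between 0 and 2 falls were called in each, and without LCN2 replicate 2 there were 16 and 19. Replication-dependent histone genes gave 0 calls among 7, with H2bc21 at -0.29 (adjusted p = 0.061) and H2bc4 at 0.18 (adjusted p = 0.16) (list adjusted p = 0.96). Targets of p53 rose in 9 of 22 members and fell in 2, with the arrest and death genes Gadd45a (1.18), Pmaip1 (0.81) and Trp53inp1 (0.74) and the p53 ligase gene Mdm2 (0.37) higher (list adjusted p = 0.0013, and adjusted p = 0.50 with an estimated correlation). In tests adjusted over the list alone, 12 p53 targets rose and 2 fell. The p53 rises numbered 4 without control replicate 3 or LCN2 replicate 3 and 2 without LCN2 replicate 1. The calls of Uhrf1, Tk1, Gins1, Mki67, Kif20a and Aurkb were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.085). The calls of Bub1b, Gadd45a and Mdm2 were lost without LCN2 replicate 1 (adjusted p of up to 0.052). Exons of Tk1, Kif20a and Gadd45a overlap those of other annotated genes.

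The list of MYC targets, which holds ribosome biogenesis genes, gave 9 rises and 1 fall among 27 (list adjusted p = 0.059). Odc1 (187 ± 18.6 to 334 ± 48.3 FPKM), a member that is not a ribosome biogenesis gene, was higher. So were Wdr43 (0.41), Npm1 (0.20) and Noc4l (0.29). For p-values adjusted over the list alone, 9 rose and 3 fell. The rises numbered 4 without control replicate 1 and 1 without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, and the median of 0.05 turned to -0.01 with values as deposited. That list passed without control replicate 1 (adjusted p = 0.0066), without LCN2 replicate 1 (adjusted p = 0.033), without a filter on low values (adjusted p = 0.042) and after GC and length correction (adjusted p = 0.048), and with an estimated correlation its adjusted p in these 4 fits was between 0.56 and 0.73. The list of cytosolic ribosomal proteins gave 4 rises among 82 members, Rpl7l1 (0.32), Rpl10a (0.29), Rpl12 (0.26) and Rpl3 (0.16). Rpl7l1, though in the list, is not a protein of the mature ribosome. The list's median was 0.09 (list adjusted p = 2.4e-05, adjusted p = 0.67 with an estimated correlation and adjusted p = 0.15 with fry for direction). The share of rises, 4 of 82, was below the 1213 of 10309 over all tested genes. Adjusted over the list alone, 2 rose, and the rises numbered 13 without LCN2 replicate 2, 2 without control replicate 1, 1 without control replicate 3 or LCN2 replicate 3 and 0 without LCN2 replicate 1. Such genes have many near-identical pseudogenes, so their values are uncertain. Proteasome genes gave 1 rise, Psmd8 (0.67), and 6 falls among 35, Psmd1 (-0.30), Psmd13 (-0.27) and Psmd3 (-0.20) among them (list adjusted p = 0.15), with 1 rise and 9 falls when adjusted over the list alone. The proteasome list passed with values as deposited (adjusted p = 0.049, and adjusted p = 0.75 with an estimated correlation) and after quantile normalization (adjusted p = 0.030, and adjusted p = 0.55 with an estimated correlation), and 0 proteasome genes were called as falls without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3. Lysosome and autophagy genes gave 4 rises among 27, Sqstm1, Gabarapl1 (0.28), Npc1 (0.24) and Ctsb (0.16) (list adjusted p = 0.12, and adjusted p = 0.023 with fry for direction), and 4 when adjusted over the list alone. The lysosome rises numbered 2 without control replicate 1, control replicate 3 or LCN2 replicate 3 and 1 without LCN2 replicate 1, and the median of 0.06 turned to -0.0043 with values as deposited. The call of Rpl3 was lost without control replicate 1, control replicate 2, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.14). The calls of Noc4l, Rpl10a, Rpl12, Psmd1, Psmd13, Psmd3, Npc1 and Ctsb were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.11). The calls of Wdr43 and Npm1 were lost without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.065). The calls of Rpl7l1 and Gabarapl1 were lost without LCN2 replicate 1 (adjusted p of up to 0.055). Exons of Wdr43, Rpl10a, Rpl12, Rpl3, Psmd1, Psmd13, Psmd3, Gabarapl1, Npc1 and Ctsb overlap those of other annotated genes.

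Iron-handling genes, of interest because LCN2 can carry iron, gave 4 rises and 4 falls among 22 (list adjusted p = 0.83; its median of -0.02 and its mean of 0.02 differ in sign). With p adjusted over the list alone, 5 rose and 5 fell, and without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 there were 1 or 2 of each. Steap1 rose from 4.14 ± 0.411 to 7.98 ± 1.25 FPKM (0.85) and Slc25a37 by 0.23. The ferritin heavy chain gene Fth1 fell from 861 ± 28.3 to 688 ± 18.6 FPKM (-0.26, adjusted p = 0.0056) and the transferrin gene Trf by 0.23. The list named for ferroptosis defence gave 3 rises, with both cystine transporter subunits Slc3a2 (0.73) and Slc7a11 (0.76) higher, and 5 falls, Fads1 and Scd2 among them (14 tested, list adjusted p = 0.83, and its test pointed down while its median of 0.03 did not). Fads1 and Scd2 also belong to the fatty acid synthesis list, and the fall of Fads1 is not read as a loss of defence. In tests adjusted over the list alone, 4 ferroptosis genes rose and 5 fell, between 0 and 2 of each were called without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, 3 falls were called without control replicate 2, and the median turned to -0.03 with values as deposited. NRF2 targets fell in 7 of 18 members and rose in 2, with G6pdx (-0.43), Gsr (-0.36) and Srxn1 (-0.32) lower and Osgin1 (0.79) higher (list adjusted p = 0.020, adjusted p = 0.50 with an estimated correlation and adjusted p = 0.067 with fry for direction). For p-values adjusted over the list alone, 3 NRF2 targets rose and 10 fell. The NRF2 falls numbered 2 without control replicate 1, control replicate 3 or LCN2 replicate 3, 0 without LCN2 replicate 1 and 11 without LCN2 replicate 2. Metallothionein and zinc genes gave 1 rise, Slc39a4 (0.32), and 1 fall, Slc39a10 (-0.28), among 5 (list adjusted p = 0.98; its test pointed up and its median was -0.08), and 2 rose and 2 fell when adjusted over the list alone. The call of Slc39a10 was lost without control replicate 1, control replicate 2, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.14). The calls of Slc25a37, Slc7a11, Fads1 and Srxn1 were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.078). The call of Slc3a2 was lost without control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.064). The call of Gsr was lost without control replicate 3 or LCN2 replicate 1 (adjusted p of up to 0.068). The calls of Trf, Scd2 and G6pdx were lost without LCN2 replicate 1 (adjusted p of up to 0.055). Exons of Slc25a37, Trf and G6pdx overlap those of other annotated genes.

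Most markers of mast cells, lymphocytes and erythroid cells were at or near 0, while some macrophage, endothelial and fibroblast markers were expressed. Of 12 mast cell markers 8 were listed at 0 in every library, and the highest was Mrgprb2 at 0.988 ± 0.0144 FPKM in control and 1.26 ± 0.206 FPKM in LCN2 libraries (0.21, adjusted p = 0.14). Markers of T, NK and B cells reached at most 0.172 FPKM and erythroid markers 0.606 FPKM. Of 15 macrophage markers, 2 were high enough to test. Cd14 rose from 7.84 ± 0.914 to 9.58 ± 0.793 FPKM (0.32, adjusted p = 0.033, and adjusted p = 0.064 without a filter), while 5 abundant leukocyte genes (Ptprc, Lyz2, Tyrobp, Laptm5 and Fcer1g, chosen after their values were seen) together summed to 0.798 ± 0.170 FPKM in control and 0.626 ± 0.0406 FPKM in LCN2 libraries. The endothelial marker Flt4 was at 3.62 ± 0.168 and 4.05 ± 0.478 FPKM (adjusted p = 0.14). Among 3 tested fibroblast markers 1 rose, Dcn, from 504 ± 30.8 to 595 ± 16.6 FPKM (list adjusted p = 0.96; its median of -0.15 and its test differ in sign). Housekeeping genes gave 0 rises and 5 falls among 15, with Actb (1464 ± 54.4 to 1241 ± 44.5 FPKM, -0.17), Tubb5 (-0.19) and Gusb (-0.19) lower under each scaling tried, though Actb did not pass after quantile normalization (list adjusted p = 0.11, and adjusted p = 0.029 after quantile normalization, or adjusted p = 0.51 there with an estimated correlation). Adjusted over the list alone, 1 rose and 5 fell, and 0 falls were called without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3. Of the nuclear and non-coding RNAs, Tug1 alone was analysed, at 33.5 ± 1.84 and 29.9 ± 0.901 FPKM (adjusted p = 0.17). The call of Gusb was lost without control replicate 1, control replicate 2, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.11). The calls of Cd14, Actb and Tubb5 were lost without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3 (adjusted p of up to 0.11). Exons of Tug1 overlap those of other annotated genes.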

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

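Array weights, a pseudocount of 0.1, filters at a mean of 0.1 and 5 FPKM, column sums, quantile normalization, no variance trend, the GC and length correction and the narrower pattern for predicted gene models were chosen after seeing the data, and the other settings before. TMM scaling was fixed before the data were examined but became the reported setting only after the values as deposited had been fitted. No called gene list and no called named gene turned in direction under the settings in which it was tested (44 lists and 155 named genes at a mean of 5 FPKM, and 166 named genes with predicted gene models left out). The pattern fixed for predicted models also left out 95 other genes, so that the mitochondrial ribosome list was tested on 52 of 78 members and the cytosolic ribosomal list on 56 of 82. With the narrower pattern all members and all 167 named genes were tested, and 2275 genes changed (1237 higher, 1038 lower). The other changed genes were not followed, and the balance of rises and falls did turn. With values as deposited, 693 genes were higher and 1680 lower, scaled to column sums 950 and 1308, and after quantile normalization 1109 and 1164. Without a filter on low values 1471 changed, 618 of them lower. Array weights gave 4185 changed (2159 higher, 2026 lower) and 442 members of lists. A fold change of at least 1 on the log2 scale left 40 (36 higher, 4 lower), an adjusted p under 0.01 left 276 (188 and 88), and treat against a fold of 1.2 left 50 (36 and 14). Leaving out 1 library gave between 268 and 3160 changed genes (179 to 1658 higher, 89 to 1502 lower) and between 49 and 369 called list members, against 276 with all libraries. The lowest came without LCN2 replicate 1 and the highest without LCN2 replicate 2. With fewer libraries fewer genes can pass, and the rise without LCN2 replicate 2 goes with its place between the groups. Of 47 lists 20 passed camera, 0 with an estimated correlation, 13 with fry for direction (11 of the 20, and the lysosome and drug efflux lists) and 42 with fry for change in either direction. Same-numbered libraries of the 2 groups did not deviate together (correlations -0.22, -0.26 and 0.0086), so the numbers were not taken as pairs. With a replicate block 262 genes changed (181 higher, 81 lower), and 52 list members. Of the 167 named genes, 111 lost their call with the block, 113 without LCN2 replicate 1, 31 without a filter and 17 with values as deposited. With no variance trend 17 lost it, after quantile normalization 9 and scaled to column sums 7. With values as deposited 1 named gene gained a call, as did 1 when scaled to column sums. The log2 difference in Lcn2 was 0.24 and became 1.04 with a pseudocount of 0.1, because the gene lies near 0. The median correlation between libraries of a group was 0.990 with a pseudocount of 0.1 and 0.992 at a mean of 5 FPKM. Where no cause is given, the cause was not tested. The count test of the design, its count-based alternatives, the thinning of libraries, the filter at a mean count of 10 and the test of library pairs for counting noise were not run, since they need counts. The unknown depth leaves the precision of genes of low value unstated.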

Other observations

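The tests of a swapped label, of leukocytes, of iron withdrawal, of endotoxin, of GC content and length, of scaling and of the number of changed genes over other splits were chosen after the results were seen, as were the 7 gene lists beginning with the aminoacyl-tRNA synthetases. Those of mixing with control material and of the number of lists over other splits were written before their results.

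Some further gene families, picked after the values of their members were seen, are described by counts alone, since a test on the same data would restate the choice. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, 14 rose and 1, Hars, fell (median log2 fold change 0.30). Of the 20, 4 belong to the integrated stress response list, and 10 of the other 16 rose, such as Farsb (0.50) and Lars (0.45). Membership of that list does not show whether the other rises are separate from the ATF4 response, which was not tested. Of 17 mitochondrial synthetase genes 0 rose and 1 fell, and the difference between these groups was not tested. Alpha and beta tubulin genes fell in 8 of 10 members, with Tubb2a (-0.56) and Tubb2b (-0.54) lowest, and 1 of the 10, Tubb5, is in the housekeeping list. The synthetase rises numbered 3 without control replicate 1 or LCN2 replicate 3, 4 without control replicate 3 and 2 without LCN2 replicate 1, and the tubulin falls between 0 and 2 without any of these libraries.

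Other families held secreted and surface proteins. Of 6 liver secretory protein genes expressed in these cells, Alb (-0.78), Afp (-0.41), Apoe (-0.32) and Trf (-0.23) fell and 0 rose, and 2 falls were called without LCN2 replicate 1. Among 20 colony stimulating factor, chemokine and interleukin genes 9 rose and 2 fell, with Csf2 (1.74), Il24 (1.03), Cxcl16 (0.88) and the mast cell growth factor gene Kitl (0.41) higher and Cxcl15 (-0.72) and Il15 (-0.48) lower. In the lists fixed beforehand were 10 of these 20 genes, 3 of the 12 integrin genes and 1 of the liver genes, Trf. Without LCN2 replicate 1 there were 3 rises of cytokine genes, and 6 without control replicate 3 or LCN2 replicate 3. Integrin genes rose in 6 of 12, led by Itga2 (1.25), in 3 without control replicate 1, control replicate 3 or LCN2 replicate 3 and in 2 without LCN2 replicate 1. Among 4 EGFR ligand genes Areg (1.00) and Hbegf (0.86) rose, and 1 rise was called without LCN2 replicate 1 or LCN2 replicate 3.

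LCN2 replicate 2 lay between the controls and the other LCN2 libraries. A swap with a control library is argued against, since 0 control libraries lay on the LCN2 side of the midpoint of the first principal component. Control material in this library may account for its place. In genes called without it, it reached a median share of 0.510 of the change among 1658 that rose and 0.530 among 1502 that fell. The difference was -0.0198 (95% interval -0.0367 to -0.0001 from a bootstrap over genes). Genes are not independent replicates, so this interval leaves out the spread between libraries. No conclusion is drawn from its place just below 0. Mixing needs the same share in both, and a difference within 0.1 had been set beforehand as meeting that. A culture that responded less fully predicts the same and stays open as the biological explanation, untested, since no dose or time is given. Over single lists the median share ran from 0.347 (citrate cycle, 6 genes, quartiles 0.16 and 0.41) to 0.669 (Wnt targets, 8 genes, quartiles 0.60 and 0.78). The spread of such medians under mixing was not computed for lists so small, and the controls themselves differ. These shares therefore do not decide whether mixing occurred. The untreated libraries also differed along the first principal component, with control replicate 2 (-8.09) nearest to the LCN2 libraries and control replicate 1 (-17.3) farthest. Control replicate 2 correlated with the LCN2 libraries at 0.986 to 0.992, and control replicate 1 at 0.978 to 0.988. The spread along this component is therefore not wholly an effect of LCN2.

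Of the ATF4 list 22 of 28 genes and of the NF-kB list 17 of 24 were called higher, but between 4 and 13 and between 9 and 15 without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3. Leukocytes in the treated samples are argued against, since 5 abundant leukocyte genes summed to 0.626 FPKM there and 0.798 FPKM in controls. These 5 genes were chosen after their values were seen. Among markers fixed beforehand, those of T, NK and B cells reached at most 0.172 FPKM. Of 15 macrophage markers fixed beforehand 2 were high enough to test, and Cd14 was called higher (0.32 on the log2 scale). Withdrawal of iron by the added protein stabilises Tfrc mRNA, but Tfrc fell by 0.43 (SE 0.10, adjusted p = 0.023), with all 3 LCN2 libraries below all 3 controls. Its adjusted p was between 0.074 and 0.089 without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3, and the log2 fold change lay between -0.54 and -0.35 over all 6 fits that left out 1 library. Endotoxin in the recombinant protein cannot be told apart from an effect of LCN2: the interferon list had a median of -0.048, but the receptor genes Tlr4, Ly96 and Cd14 were expressed (8.15, 6.56 and 7.84 FPKM in controls), and no control protein was used here.

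In the cholesterol, fatty acid, S phase and G2/M lists 16 of 25, 7 of 13, 11 of 30 and 11 of 30 genes were called lower, but at most 7 in any of them without control replicate 1, control replicate 3, LCN2 replicate 1 or LCN2 replicate 3. A bias by GC content and length is argued against as the whole cause, since the median of the 98 members of these 4 lists was -0.22 after correction and -0.21 before. The choice among the 5 scalings tried is argued against as the whole cause as well. The smallest median fall over them was -0.21, while the shift of all genes between scalings spanned 0.057. Both tests were chosen with the falls of these lists already known, so they describe the falls and lend them no independent support. Whether the cells respond to LCN2 in this way stays open and was not tested.

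The 6 libraries can be split into equal groups in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave as many as 2216 changed genes, and the highest of the others gave 5. For the gene lists, 20 passed camera in the real split, and 2 of the 10 splits gave as many. The highest of the others gave 21, with control replicates 1 and 3 and LCN2 replicate 2 against the rest. Each other split still holds more control libraries on one side than on the other. It therefore keeps part of the treatment difference between its groups and has the rest within them. The other splits are thus not free of treatment. All of them hold such an imbalance, yet they gave between 2 and 21 lists. The treatment left in them therefore does not by itself account for the 21. The number of lists also followed which libraries were put together. Neither count can tell the treatment from other differences between these libraries.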
